A study of Mus musculus with 6 samples.

How the data were processed

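RNA was sequenced from 6 cultures of mammary gland stromal fibroblasts, 3 Sharpin-cpdm and 3 wild type, each from the pooled glands of 3 mice. Per the labels' protocols, cells were isolated by collagenase digestion and differential centrifugation, grown in serum-containing medium to confluence, freed of floating cells and lysed in the wells, and libraries were made with the TruSeq RNA v2 kit, which does not mark the strand of the transcript. Per the submitters' processing notes, bcl2fastq 1.8.4, TopHat2 2.0.10 and HTSeq 0.5.4p3 were used with the mm10 build; the role of each tool, the gene annotation, the read length and the strand and overlap settings of the counting were not given in the sources used here. The authors deposited 1 table of counts per library, in whole reads per gene symbol, with 23337 gene rows and 5 summary rows of the counting program.

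The summary rows were kept out of library sizes and tests. They held between 48.8% and 51.2% of the entries of a table, most of them alignments that were not unique, which can count a read more than once and came to between 0.831 and 0.923 per count assigned to a gene. Entries outside any gene came to between 11.7% and 12.7% of the gene counts, and ambiguous ones to between 0.608% and 0.627%. Reads that align to several places are therefore missing from genes with near-identical copies, and those genes are less certain, as are overlapping genes. The tables held 0 of the 13 listed mitochondrially encoded genes, so that list was not analysed here. Depth was even, from 13570649 to 15656196 gene counts per library, and the 10 most abundant genes took between 11.3% and 12.8% of them.

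Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were filtered with filterByExpr by group, which left 13442 of 23337, and libraries were scaled by TMM factors between 0.969 and 1.03. The test fixed before the data were examined was edgeR's quasi-likelihood F-test of genotype without other terms, two-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Standard errors are the size of the log2 fold change divided by the square root of F. CPM values use the TMM-scaled library sizes, and log2 CPM used for gene lists and correlations has a prior count of 2. Libraries of a group were compared for duplicates by a chi-square test of their counts: the statistic per degree of freedom was between 17.8 and 90.0, and no pair of libraries fell within sampling noise.

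The groups share the replicate numbers 1 to 3 in the labels, which do not say what a number marks. The fit with the number as a block was listed before the data were examined. Deviations of log2 CPM from the group means, correlated across genes (which are not independent replicates), gave 0.457, 0.809 and 0.737 for the same-numbered libraries 1, 2 and 3, and between -0.691 and 0.00677 for the other combinations. Same-numbered libraries correlated more strongly than every other combination, so the numbers were taken to pair the samples. This comes from the data and not from the labels. Deviations of 3 libraries from their mean sum to 0, so positive values for same-numbered libraries bring negative ones among the other combinations. As 3 libraries can be matched with 3 in few ways, these values cannot exclude a match by number that arose by chance. The biological coefficient of variation was 0.217 without the block and 0.0718 with it, and results with the block are printed wherever it changed a call.

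Fold changes of 1.5, 2 and 4 were put into 200 genes of counts simulated from the means and library sizes of the 13442 genes, to check both fits of the genotype comparison. Without the block 0%, 38.8% and 72.7% of the genes changed by 1.5, 2 and 4-fold were recovered with 0 false calls. With the block 65.7%, 89.6% and 100% were recovered, with 12 false calls in all. Both fits were run on the same counts, which were simulated with pairs, so the check assumes the pairing and favours the block.

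There were 34 gene lists, covering matrix, adhesion, signalling, inflammation, growth factors, cell cycle, metabolism, RNA quality and other cell types, fixed before the data were examined, and 31 had at least 5 tested members. Each was tested with camera on log2 CPM at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. Counts "adjusted over the list alone" use edgeR's p with the adjustment run within the list. Members can belong to more than 1 list.

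Genes were named by a rule fixed before the data were examined. It takes Sharpin, Rnf31 and Rbck1; among called genes with groups that did not overlap, a mean of at least 5 CPM and a symbol that is not a predicted gene, the 12 largest rises, the 12 largest falls and the 5 smallest p in each direction; from each list up to 4 called members with the smallest p, or up to 2 members where none was called; and Col1a1, Col1a2 and Col3a1. As the fit without the block called 0 genes, the rule was applied to the fit with the block, a choice made after the results were seen; 9 higher and 51 lower genes met its second part. Of the genes that the rule gives, those of 6 lists without a call (antigen presentation, endoplasmic reticulum stress, ribosomal proteins, immediate early genes, luminal and lymphocyte markers) and 2 others are not named here. Other names are said to have been chosen after their values were seen.

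Gene positions come from GENCODE release 21 for mouse, on the same build as the counts. A symbol matched directly for 20915 genes and through an older symbol from RefSeq for 1915. GC content and transcript length were known for 13297 of the 13442 tested genes (98.9%), and loess offsets on both were fitted per library and used with the block. Alternatives covered normalization, the low-count filter, the test, the threshold, the block, gene list settings and the removal of each library; those for the fit with the block, the GC and length offsets, the removal of each pair and of vascular and macrophage marker genes were added after seeing the data. Without the block, p-values over 3 pools per group reflect the spread between these pools. With the block, p-values and standard errors reflect only the spread left within the 3 pairs, as the spread between pairs is taken out. A permutation test of 3 against 3 cannot give a p under 0.1, so none was run on single genes.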

Results

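RNA sequencing was carried out on stromal fibroblasts cultured from the mouse mammary gland, 3 samples from Sharpin-cpdm animals and 3 from wild-type animals of the C57BL/KaLawRij strain. The cpdm allele (chronic proliferative dermatitis) is a spontaneous frameshift mutation of Sharpin, which encodes a subunit of the linear ubiquitin chain assembly complex (LUBAC) that also binds and inhibits integrins. Each sample pooled the glands of 3 mice aged 7 weeks, so that the 3 replicates of a group are separate pools and their spread covers differences between pools as well as library preparation. Cells were freed with collagenase, enriched by differential centrifugation and grown to confluence at passage 0. Counts assigned to genes came to 13570649, 13796299 and 14940100 in Sharpin-cpdm libraries 1 to 3, and to 13642440, 15656196 and 14226644 in wild-type libraries 1 to 3. Between 16221 and 16495 of the 23337 listed genes had at least 1 count in a library, and 13442 passed the low-count filter and were tested. The design asks which transcripts of the gland's stromal fibroblasts differ when SHARPIN is missing, with collagen and duct growth as the setting that the series names.

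Sharpin itself, at 76347040 to 76351111 on the minus strand of chromosome 15 (mm10, GENCODE ENSMUSG00000022552.16), was lower in every Sharpin-cpdm library. Its normalized counts were 10.3, 9.43 and 9.25 CPM (counts scaled to a common library size) in the Sharpin-cpdm libraries and 24.2, 25.8 and 31.3 CPM in the wild-type libraries. The log2 fold change was -1.49 ± 0.14 (SE, n = 3 per group), with an adjusted p of 0.272 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With the replicate number as a block, it was -1.48 ± 0.12 with an adjusted p of 0.00598 in the same test. The transcripts of the other LUBAC subunits passed in neither fit. With the block, Rnf31, the catalytic subunit, had a log2 fold change of -0.07 ± 0.08 and Rbck1 one of 0.13 ± 0.04, with adjusted p of 0.701 and 0.223 in edgeR's test.

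Wild-type and Sharpin-cpdm cultures differed mainly by transcripts that were lower in the mutant. Saa3, Dpp4, Eln, 4 of 18 complement genes, 8 of 46 growth factor and receptor genes and 14 of 19 endothelial markers fell, while Map3k14, Nfkb2, 6 of 18 contractile and 3 of 44 cell cycle genes rose. With an estimated correlation 0 gene lists were called as a whole (smallest adjusted p = 0.358 with an estimated correlation). In edgeR's test these differences passed the threshold only when each Sharpin-cpdm library was compared with the wild-type library of the same replicate number. Without that block, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes in either direction, with 307 of 13442 genes at an unadjusted p under 0.05, where chance alone gives 672. DESeq2 without the block called 10 genes, 2 higher (Map3k14 and Ltc4s) and 8 lower (Sharpin, Sparcl1, Pi15, Cdh13, Papln, Exoc3l, Ramp3 and Cacna1g), and limma-voom called 0 with 272 at an unadjusted p under 0.05. With the block, edgeR's test called 337 genes, 53 higher and 284 lower, and 84.3% of the calls were lower. All 337 moved in the same direction in all 3 pairs, which largely follows from a call over 3 pairs. Of them, 72 changed by at least 2-fold, 4 higher and 68 lower. The CPM of the groups did not overlap for 70 of the 337 calls and for 5.91% of all tested genes. Chance gives 10% for libraries that are not paired, a share that spread between pairs lowers. Offsets for GC content and gene length, added to the block, gave 147 higher and 285 lower genes, which brings the lower share to 66.0%. The count rested on the pairs used: 653 genes (134 higher, 519 lower) were called without pair 1, 128 (9 higher, 119 lower) without pair 2 and 44 (3 higher, 41 lower) without pair 3. In the rest of the text, a gene is said to have risen or fallen where edgeR's test with the block called it; without the block, no such gene had an adjusted p under 0.272.

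**Figure D1:**
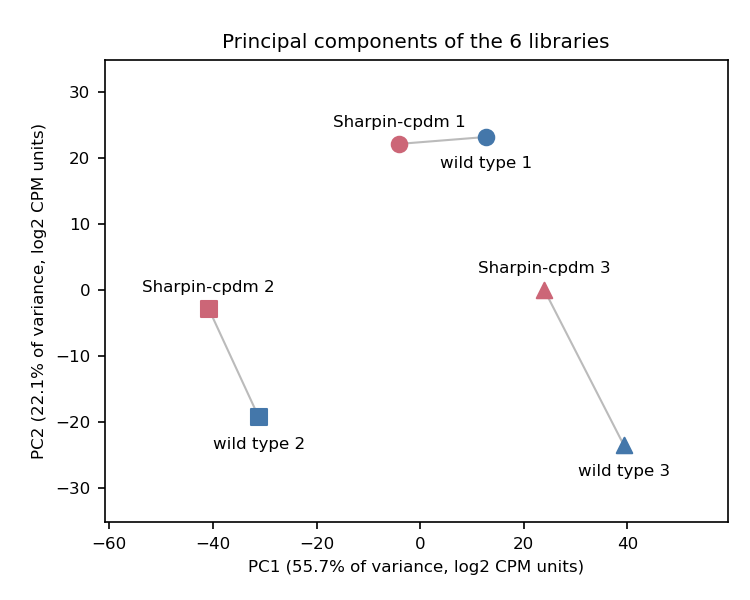
Principal components of log2 CPM over the 13442 tested genes, with PC1 (55.7% of the variance) on the horizontal and PC2 (22.1%) on the vertical axis, both in log2 CPM units. Colours give the genotype (red Sharpin-cpdm, blue wild type), symbols the replicate number, and grey lines join the libraries that share one. Along PC1 the pairs lie apart, with pair 2 lowest and pair 3 highest. Within each pair the Sharpin-cpdm library also lies lower on PC1 than the wild-type one. The values are -4.00 and 12.7 in pair 1, -40.8 and -31.1 in pair 2, and 23.9 and 39.3 in pair 3.

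Among genes whose groups did not overlap and whose mean was at least 5 CPM, the largest rise was that of Map3k14, which encodes NIK, the kinase that starts the non-canonical NF-kappaB pathway. Map3k14 (chromosome 11, 103219762 to 103267472, minus strand) stood at 65.0 ± 6.24 CPM (mean ± SD, n = 3) in Sharpin-cpdm and 24.5 ± 5.23 CPM in wild type, a log2 fold change of 1.41 ± 0.12 with an adjusted p of 0.00598 in edgeR's test with the block. Nfkb2, the precursor that this pathway processes, rose by 0.47 ± 0.08 with an adjusted p of 0.0363. Psrc1 and Bub1b, with roles at the mitotic spindle, rose by 0.72 ± 0.10 and 0.41 ± 0.07, and the neuronal guidance gene Flrt3, Elfn1, Limd2, the cathepsin inhibitor Cstb and the actin regulator Synpo rose by between 0.27 and 0.64. Ltc4s, which makes leukotriene C4 and was singled out after its values were seen, rose by 2.41 ± 0.33 from wild-type values of at most 1.04 CPM. Annotated genes overlap several of these: 1700028N14Rik overlaps Map3k14 and Psd overlaps Nfkb2, and no strand setting was given for the counts.

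The largest fall was that of Saa3, an acute-phase apolipoprotein (chromosome 7, 46711998 to 46715700, minus strand), at -5.04 ± 0.41 on the log2 scale with an adjusted p of 0.00598 in edgeR's test with the block. Its level varied widely between replicates, at 3.48, 2.84 and 22.4 CPM in Sharpin-cpdm libraries 1 to 3 and 25.2, 94.4 and 1063 CPM in wild-type libraries 1 to 3, and similar Saa genes lie nearby, so that only reads placed at 1 position count for it. Dpp4, a membrane-bound peptidase of fibroblasts, had a log2 fold change of -1.59 ± 0.10, from 29.8, 28.3 and 65.4 CPM in wild-type libraries 1 to 3 to 9.29, 11.5 and 19.6 CPM in Sharpin-cpdm libraries 1 to 3. Stc1, a secreted glycoprotein hormone, changed by -1.33 ± 0.11, Dio2, which activates thyroid hormone, by -1.26 ± 0.14, and Agtr1a, an angiotensin II receptor, by -1.01 ± 0.13. Il13ra2, a decoy receptor of interleukin 13, changed by -1.19 ± 0.19, and the matrix protein gene Papln, Rerg, Kif26a, Sncaip and Prex2 by between -1.14 and -1.04. Eln, which encodes elastin, fell from 376 ± 46.1 to 237 ± 47.9 CPM with a log2 fold change of -0.68 ± 0.05. In the same libraries 14 of 19 endothelial markers fell, and the median log2 fold change of all 19 was -0.78.

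**Figure D2:**
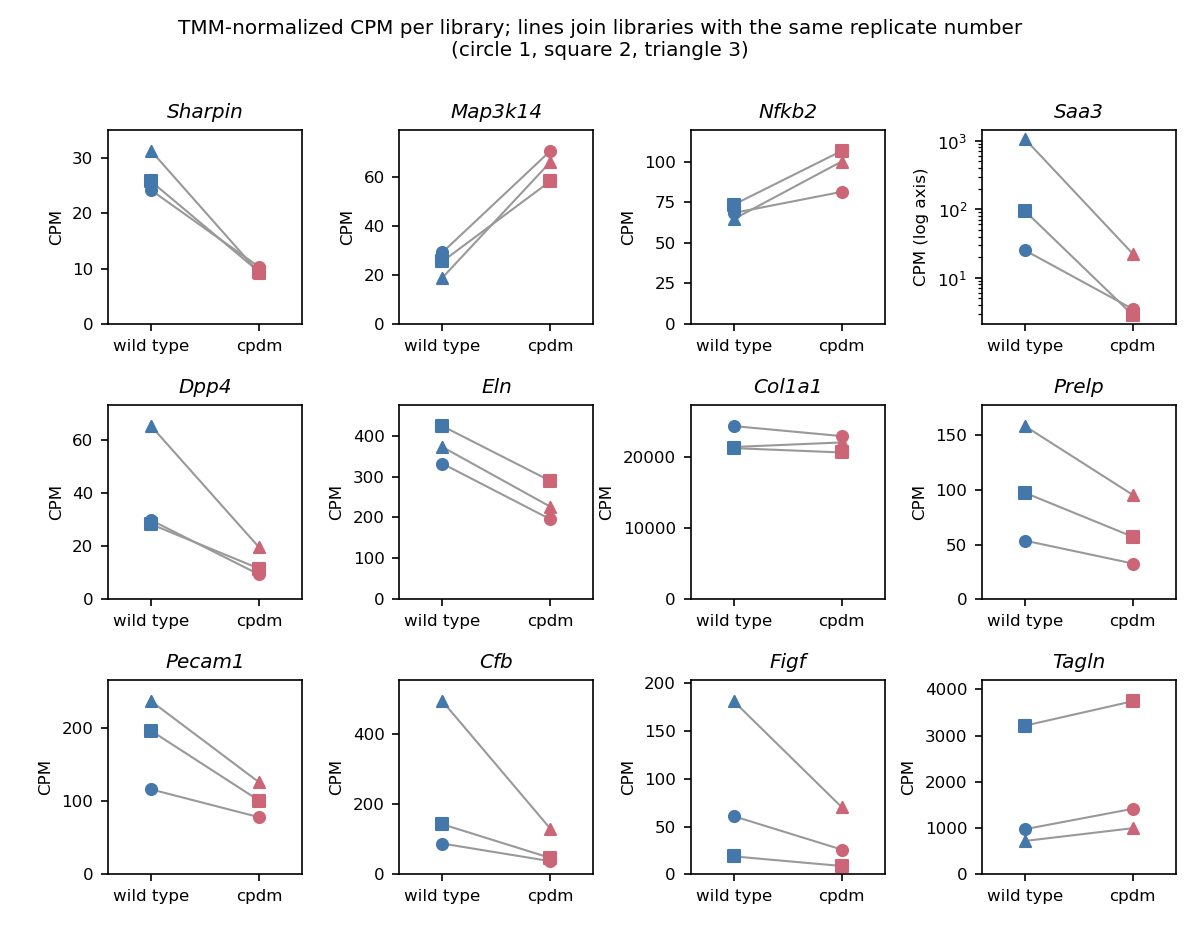
CPM of 12 genes per library (vertical axis, logarithmic for Saa3 and starting at 0 for the others) in wild type (blue) and Sharpin-cpdm (red), with grey lines between libraries of the same replicate number and symbols for that number. Sharpin fell from between 24.2 and 31.3 to between 9.25 and 10.3 CPM, and Saa3 fell in each pair although its level ranged from 25.2 to 1063 CPM within wild type.

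Col1a1 and Col1a2 transcripts differed between genotypes by less than the spread between replicates, while 6 of the 40 tested genes for fibrillar collagens and their assembly fell. Col1a1 stood at 21944 ± 1166 CPM in Sharpin-cpdm and 22405 ± 1753 CPM in wild type (log2 fold change -0.03 ± 0.05, adjusted p 0.826 in edgeR's test with the block), and Col1a2 had a log2 fold change of 0.02 ± 0.05 with an adjusted p of 0.861. Col3a1 had -0.39 ± 0.08 with an adjusted p of 0.0598. Of the 40, 0 rose and 34 did not pass, 12 had a log2 fold change above 0, and 4 rose and 11 fell when p was adjusted over the list alone. Prelp and Lum, small leucine-rich proteoglycans that bind collagen, changed by -0.74 ± 0.05 and -0.71 ± 0.07, Adamts2, which removes the amino-terminal propeptide of procollagen, by -0.45 ± 0.06, and Tnxb, tenascin X, by -1.20 ± 0.16. The other 2 were Dcn, decorin, and Col12a1, at -0.90 and -0.32, named after their values were seen. The list as a whole was lower with the block (camera adjusted p = 0.0273), with an adjusted p of 0.183 without it and adjusted p = 0.358 with an estimated correlation. Without pair 1 its adjusted p was 0.0503 and without pair 3 it was 0.105. Of the 18 fibroblast markers, 7 fell and 0 rose (14 and 1 adjusted over the list alone), Lum and Dcn among them, and beside them 14 of 19 endothelial markers fell, with a median log2 fold change of -0.78 over all 19.

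Of 30 basement membrane and network collagen genes 3 fell and 0 rose. The list had a camera adjusted p of 0.00474 with the block, and adjusted p = 0.358 with an estimated correlation. Sparcl1, a matricellular protein also made by vessel cells, had a log2 fold change of -0.64 ± 0.07, from 436 ± 8.01 to 280 ± 29.6 CPM, and Nid2 and Lama4, basement membrane components, had -0.40 ± 0.04 and -0.37 ± 0.05. Adjusted over the list alone, 1 rose and 8 fell. Of 44 matrix proteases and inhibitors, 8 fell and 1 rose, and 23 fell and 2 rose adjusted over the list alone. Besides Dpp4, Adamts15, a proteoglycanase, changed by -1.26 ± 0.09 and the collagenase Mmp13 by -0.63 ± 0.08, whereas Mmp9, a gelatinase, rose by 0.65 ± 0.07. Mmp3 and Mmp2, named after their values were seen, changed by -1.10 ± 0.16 and -0.60 ± 0.08. The camera adjusted p of this list was 1.04e-04 with the block, and adjusted p = 0.358 with an estimated correlation. In the same libraries 14 of 19 endothelial markers fell, and the median log2 fold change of all 19 was -0.78.

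Of the integrin and focal adhesion genes 3 passed the threshold, and 6 of 18 genes of the contractile apparatus rose. Of 19 integrins, Itgb3 alone fell, at -0.42 ± 0.04, with 5 lower and 1 higher adjusted over the list alone. The integrin list had a camera adjusted p of 0.128 with the block and of 0.0159 without it (adjusted p = 0.344 with an estimated correlation), and fry, which tests for movement in 1 direction without comparing with other genes, gave 0.0272 with the block. Of 31 integrin activity and focal adhesion genes, Sharpin fell and Actn1, alpha-actinin, rose by 0.30 ± 0.05, with 2 lower and 7 higher adjusted over the list alone and a camera adjusted p of 0.0679. Of 18 myofibroblast contractile genes, 6 rose and 0 fell (9 and 0 adjusted over the list alone), with Tagln at 0.41 ± 0.07, Actg2 at 0.44 ± 0.08 and Cnn2 at 0.28 ± 0.05 beside Actn1. The camera adjusted p was 6.71e-05 with the block, with 0.128 without it and adjusted p = 0.358 with an estimated correlation. Levels of these genes also differed between pairs, with Tagln at 720 to 3217 CPM over the wild-type libraries. In the same libraries 14 of 19 endothelial and 7 of 18 fibroblast markers fell, and the median log2 fold changes of all 19 and all 18 were -0.78 and -0.29. Of 23 TGF-beta and YAP target genes, Eln and Tgfbr3, the co-receptor betaglycan (-0.62 ± 0.04), fell and 0 rose, with 3 lower and 2 higher adjusted over the list alone and a camera adjusted p of 0.829.

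Genes of LUBAC and TNF receptor signalling differed only by Sharpin itself, the single call among 26 genes in both adjustments, that over all genes and that adjusted over the list alone (camera adjusted p 0.0849 with the block). NF-kappaB target genes moved both ways. Of 29 tested, Nfkb2 rose and 3 fell: Saa3, the neutrophil chemokine Cxcl5 (-1.16 ± 0.12) and the atypical inhibitor Nfkbiz (-0.53 ± 0.07). Adjusted over the list alone, 5 rose and 5 fell, and the camera adjusted p was 0.976, with a median log2 fold change of -0.00378. Of 28 cytokines and chemokines, Cxcl5 and the scavenger receptor Cxcr7 (-1.06 ± 0.17) fell and 0 rose, with 5 lower and 2 higher adjusted over the list alone and a camera adjusted p of 0.128. In the type I interferon list of 38 genes, Ifi27l2a alone fell (-1.64 ± 0.29), with 2 lower and 2 higher adjusted over the list alone and a camera adjusted p of 0.155. None of 17 antigen presentation genes passed in edgeR's test with the block, and 3 were lower and 2 higher adjusted over the list alone (camera adjusted p 0.735).

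Of 18 complement genes 4 fell and 0 rose, and 12 fell and 0 rose adjusted over the list alone. The list had a camera adjusted p of 2.43e-06 with the block, and adjusted p = 0.358 with an estimated correlation. Cfb, complement factor B of the alternative pathway, had a log2 fold change of -1.62 ± 0.12 with an adjusted p of 0.00598 in edgeR's test with the block, from 87.6, 143 and 495 CPM in wild-type libraries 1 to 3 to 37.2, 46.5 and 130 CPM in Sharpin-cpdm libraries 1 to 3. C4b changed by -0.83 ± 0.12, C2 by -0.52 ± 0.07 and Serping1, the C1 inhibitor, by -0.61 ± 0.08. Cfb and C2 are neighbours that share an overlapping annotated gene, and C4b has a near-identical copy, so their counts are less certain. The median log2 fold change of the list was -0.55, beside -0.78 for the endothelial markers.

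Of 46 growth factors and receptors of the mammary stroma 8 fell and 0 rose, and 16 fell and 3 rose adjusted over the list alone. The list had a camera adjusted p of 6.89e-04 with the block, and adjusted p = 0.358 with an estimated correlation. Figf, which encodes the lymphangiogenic factor VEGF-D, had a log2 fold change of -1.27 ± 0.06 with an adjusted p of 0.00331 in edgeR's test with the block, at 60.8, 18.7 and 181 CPM in wild-type libraries 1 to 3 and 25.8, 8.61 and 70.4 CPM in Sharpin-cpdm libraries 1 to 3. Pgr, the progesterone receptor, changed by -0.84 ± 0.07, Bmp2 by -0.98 ± 0.10 and Igfbp4, which binds insulin-like growth factors, by -0.61 ± 0.08. Sfrp2, Igf1 and Fgf7, named after their values were seen, changed by -1.01 ± 0.14, -0.53 ± 0.07 and -0.35 ± 0.06. Endothelial markers, 14 of 19 of which fell, moved in the same direction.

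All 44 tested cell cycle genes had a log2 fold change above 0, by small amounts. Ccnd1, cyclin D1, rose by 0.42 ± 0.04 from 69.2 ± 11.6 to 92.6 ± 15.8 CPM, the spindle checkpoint kinase Bub1b by 0.41 ± 0.07 and Prc1, a midzone microtubule protein, by 0.29 ± 0.04. These 3 rose over all genes and 34 rose adjusted over the list alone, with 0 lower. The list had a median log2 fold change of 0.25 and a camera adjusted p of 8.51e-17 with the block, and adjusted p = 0.358 with an estimated correlation. All 23 cholesterol synthesis genes were likewise higher, with 0 called in edgeR's test with the block, 9 higher and 0 lower adjusted over the list alone, a median of 0.21 and a camera adjusted p of 2.43e-06 (adjusted p = 0.505 with an estimated correlation). Sqle, squalene epoxidase, stood at 0.26 ± 0.07 with an adjusted p of 0.127 in edgeR's test with the block. Endothelial, pericyte and fibroblast markers had median log2 fold changes of -0.78, -0.43 and -0.29 in the same libraries. Ribosomal protein genes had 0 calls of 34 in both adjustments and a median of 0.08 (camera adjusted p 0.00253 with the block, and adjusted p = 0.358 with an estimated correlation). Of 27 apoptosis and p53 target genes, Ccng1 rose by 0.28 ± 0.04, the single call in both adjustments (camera adjusted p 0.0849), and of 28 hypoxia and glycolysis genes the vasodilator gene Adm fell, at -0.94 ± 0.12, again the single call in both (0.242). Endoplasmic reticulum stress genes (23 tested, camera adjusted p 0.179) and immediate early and heat shock genes (17 tested, 0.711) had 0 calls in both adjustments.

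**Figure D3:**
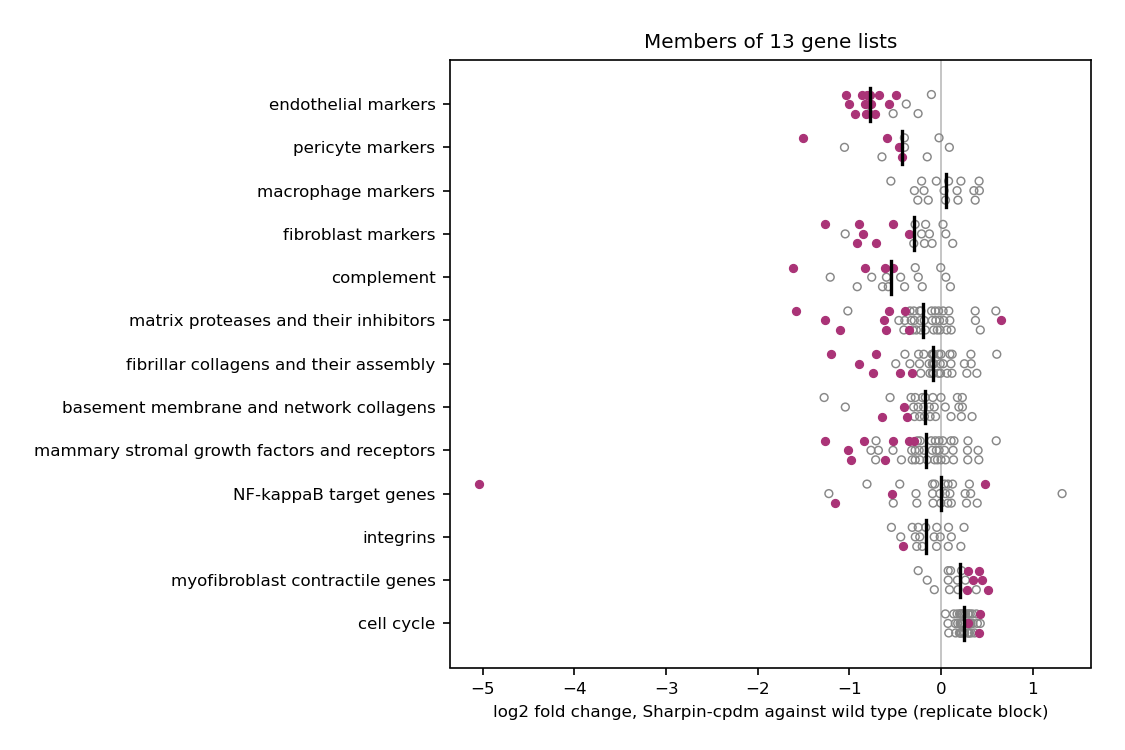
Log2 fold change of Sharpin-cpdm against wild type (horizontal axis, edgeR with the replicate block) for the tested members of 13 gene lists (vertical axis), with filled points for genes at an adjusted p under 0.05, open points for the others and a black bar at each list's median. The endothelial median lies at -0.78, the complement median at -0.55 and the cell cycle median at 0.25.

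Markers of other cell types that the digested gland could leave in the cultures were measured in the same libraries. Endothelial markers were lower: all 19 had a log2 fold change below 0, 14 fell and 0 rose (16 and 0 adjusted over the list alone), and the camera adjusted p was 5.46e-14 with the block, with adjusted p = 0.358 with an estimated correlation. Pecam1 stood at 78, 101 and 126 CPM in Sharpin-cpdm libraries 1 to 3 and 116, 196 and 236 CPM in wild-type libraries 1 to 3, a log2 fold change of -0.82 ± 0.08, and Tek, Cldn5 and Flt1 changed by -0.81 ± 0.07, -1.01 ± 0.09 and -0.72 ± 0.07. Of 11 pericyte markers, 4 fell and 0 rose (6 and 0 adjusted over the list alone), with Steap4 at -1.50 ± 0.17, Abcc9 at -0.59 ± 0.08, Notch3 at -0.45 ± 0.07 and Mcam, which endothelial cells also express, at -0.43 ± 0.08 (camera adjusted p 5.26e-04, and adjusted p = 0.358 with an estimated correlation). Fibroblast markers were lower too, with 7 of 18 called, among them Cd34 at -0.92 ± 0.07, Ly6a at -0.85 ± 0.08, Lum at -0.71 ± 0.07 and Fbln1 at -0.52 ± 0.05 (camera adjusted p 2.43e-06, and adjusted p = 0.358 with an estimated correlation). Among 13 adipocyte markers, Fabp4 (-0.93 ± 0.06), which capillary endothelium also makes, and Lpl (-0.87 ± 0.12) fell, with 2 lower and 1 higher adjusted over the list alone (camera adjusted p 0.155). Of 5 granulocyte and mast cell markers, Kit fell (-0.91 ± 0.08), with 4 lower adjusted over the list alone (camera adjusted p 6.37e-04, and adjusted p = 0.358 with an estimated correlation).

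Macrophage markers passed in neither direction: 0 of 17 were called in edgeR's test with the block or adjusted over the list alone, the median was 0.05, and the camera adjusted p was 0.348. The pairs went different ways: the median log2 difference of the 14 macrophage markers with at least 5 CPM was 0.56, -0.26 and 0.23 in pairs 1, 2 and 3, and without pair 2 the list was higher with a camera adjusted p of 1.64e-04. Of its members with the smallest p, Cd14 stood at -0.55 ± 0.15 with an adjusted p of 0.144 and Laptm5 at 0.42 ± 0.13 with 0.175. Of 9 Schwann and neural markers, 1 rose and 0 fell, and 4 rose and 0 fell adjusted over the list alone (camera adjusted p 0.00253, and adjusted p = 0.358 with an estimated correlation). Basal epithelial and keratinocyte markers had 0 calls of 13 in both adjustments and a median of -0.52 (camera adjusted p 0.00521, and adjusted p = 0.372 with an estimated correlation), with Krt5 at a log2 fold change of -0.85 ± 0.29 and Oxtr at one of -1.24 ± 0.41. Luminal epithelial markers had 0 calls of 17 in both adjustments (camera adjusted p 0.197). Skeletal muscle markers had 0 calls of 13 over all genes, and 1 fell and 0 rose adjusted over the list alone. The camera adjusted p of this list was 0.0440 with the block (adjusted p = 0.803 with an estimated correlation). Without pair 1 the list pointed upward with a camera adjusted p of 0.219. Myh1 and Myh4, myosin heavy chains of fast muscle, had the smallest p there, at -0.90 ± 0.19 and -0.91 ± 0.27. Of 2 lymphocyte markers that passed the filter, 0 were called, and the list was too short for camera. Counts of the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were 0 in each library, and Xist, the only tested sex-linked gene, stood at 569 ± 63.4 CPM in wild type and 490 ± 23.8 CPM in Sharpin-cpdm.

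Of the 31 lists tested with camera, 15 were called without the block (4 higher, 11 lower) and 16 with it (5 higher, 11 lower). With an estimated correlation 0 were called in either fit, with smallest adjusted p of 0.344 and 0.358, and fry called 0 without the block and the integrin list alone with it. Leaving out each pair in turn, 14 of the 16 kept their call and direction each time, the exceptions being the fibrillar collagen and skeletal muscle lists. Lists without a call over all pairs passed for cytokines (0.0125, lower), hypoxia (0.00504, lower) and luminal markers (3.57e-07, lower) without pair 1, for macrophage markers without pair 2, and for LUBAC (0.0281), interferon response (0.00105) and endoplasmic reticulum stress (0.0126), all higher, without pair 3. Of the 69 called genes that the naming rule gave, 69 were also called without pair 1, 36 without pair 2 and 21 without pair 3. All 69 kept their direction each time, which their shared direction in all 3 pairs had all but fixed.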

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

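The alternatives for the fit with the block, apart from the block itself, were chosen after seeing the data. Without the block, DESeq2 called 2 higher and 8 lower genes and Sharpin at -1.48, and the replicate block gave 53 and 284 with Sharpin at -1.48, since it removes the spread between pairs; every other setting called 0, leaving out each library included. With the block, the higher and lower counts were 116 and 386 with no low-count filter, 147 and 285 with GC and length offsets, 1 and 53 at an adjusted p under 0.01, 4 and 68 at an absolute log2 fold change of at least 1, and 0 and 0 with no replicate block. Leaving out each pair gave between 3 and 134 higher and between 41 and 519 lower genes. DESeq2 and limma-voom with the block called 337 and 379 genes, 271 and 334 of them shared with edgeR's 337. Other scalings with the block called 336 and 365, a CPM of at least 1 called 330, and 316 (53 and 263) were called without endothelial, pericyte and macrophage marker genes. Of edgeR's 337 calls, 319 were still tested there with the same direction, so most of that drop was the removed genes themselves. Removing them leaves the RNA of their cells in all other genes, so that setting does not bear on cell share. The cause of the other shifts was not tested.

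Camera called 15 lists without the block, 0 with an estimated correlation and 0 with fry, and the fibrillar collagen list had adjusted p = 0.0273 with the replicate block. In settings that kept all 6 libraries, directions turned for lists that passed neither before nor after: focal adhesion genes with fry (0.939), antigen presentation with the block (0.735), and NF-kappaB targets with DESeq2 size factors (0.979), a CPM of at least 1 (0.986), the block (0.976), fry (0.939) and voom weights (0.989). Leaving out each library without the block, the list adjusted p ranged, among those that turned, from 0.0547 to 0.961 for focal adhesion, 2.09e-04 to 0.421 for contractile genes, 0.103 to 0.972 for TGF-beta and YAP targets, 0.116 to 0.9745 for NF-kappaB targets, 0.00506 to 0.544 for cytokines, 5.19e-11 to 0.544 for interferon response, 0.00141 to 0.651 for antigen presentation, 0.0638 to 0.408 for hypoxia, 0.0464 to 0.850 for endoplasmic reticulum stress, 0.0963 to 0.847 for immediate early genes, 0.00163 to 0.651 for luminal markers, 7.95e-04 to 0.850 for macrophage markers and 1.79e-05 to 0.155 for skeletal muscle markers. Without wild-type library 1 the skeletal muscle list turned from lower to higher (0.0195), called in both, and the macrophage list turned from higher to lower and passed (0.00412). The log2 fold change ranged from -0.19 to 0.10 for Rnf31, -0.0656 to 0.0374 for Col1a1, -0.0110 to 0.0755 for Col1a2, -2.52 to 0.19 for Tnxb, -2.56 to 0.0573 for Adamts15, -0.44 to 1.28 for Tagln, -0.78 to 1.69 for Actg2, -1.09 to 0.0919 for C2, -2.05 to 0.41 for C4b, -1.64 to 0.00381 for Ly6a and -0.0247 to 0.97 for Laptm5. The turns of Tnxb, Adamts15, C2, C4b and Ly6a came without wild-type library 3, and those of Tagln, Actg2 and the contractile list without that library or Sharpin-cpdm library 2. A library left out without the block unbalances the pairs, and the cause of each turn was not tested further.

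The other 94 of 105 named genes and 18 of 31 lists kept their direction in every setting run without the block and in the block fit, and 92 of the 105 were called with the block. With 3 pools per group, edgeR's fit without the block recovered 0% of 1.5-fold and 38.8% of 2-fold changes in counts simulated with pairs. DESeq2 without the block called some genes below 2-fold in the real counts, such as Sparcl1 at -0.63 on the log2 scale.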

Other observations

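The tests of a lower share of endothelial or minor cells, for the acute-phase genes too, and that of the contractile list between pairs were chosen only after the results were seen; the added gene lists and the pattern each other test bears on, apart from the splits of the samples, also came from these data. Beyond the fixed lists, which held 64 of the 284 lower and 13 of the 53 higher genes, the falls included more genes of vessels and of the acute phase, named here after their values were seen. The Notch ligand Dll4 and receptor Notch4, both active in endothelium, had log2 fold changes of -0.79 ± 0.07 and -0.71 ± 0.07, Cd93 had -0.70 ± 0.07, the capillary lipase anchor Gpihbp1 had -1.15 ± 0.09, the endothelial nitric oxide synthase Nos3 had -0.86 ± 0.10 and Robo4 had -0.90 ± 0.10. Of acute-phase genes, Serpina3n stood at 92.6, 92.8 and 548 CPM in wild-type libraries 1 to 3 and 29.4, 30.4 and 182 CPM in Sharpin-cpdm libraries 1 to 3, with a log2 fold change of -1.62 ± 0.05 and the smallest adjusted p of edgeR's test with the block (1.84e-04). Hp, haptoglobin, changed by -1.76 ± 0.15 and Ptx3, pentraxin 3, by -0.74 ± 0.05. Within pairs 1, 2 and 3 the median log2 difference of the 17 endothelial markers with at least 5 CPM was -0.49, -0.85 and -0.86, and that of the 270 other lower genes was -0.60, -0.69 and -0.81.

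Levels of lists that mark kinds of cells and states differed between pairs. The SD between the means of the 3 pairs was above the central 95% of 10000 random lists matched on size and expression for 23 of 31 lists. Members of a list move together more than random genes do, so these percentiles are not a calibrated test. Macrophage markers deviated by -1.04, 0.905 and 0.134 on the log2 scale in pairs 1, 2 and 3, interferon response genes by -0.163, -0.535 and 0.698, and skeletal muscle markers by 0.632, -0.306 and -0.326. The contractile list deviated by -0.116, 0.642 and -0.526 and reached percentile 100, as did 10 other lists, and 7 lists had a larger SD. The difference between pairs is therefore not particular to a myofibroblast state, and the labels do not say what the replicate numbers mark.

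The lower level of the endothelial markers was weighed against GC content and gene length, and with offsets for both the median of the markers was -0.74 beside -0.78, which argues against that bias. A lower share of every minor cell type is argued against by the macrophage markers, whose median lay 0.849 above the endothelial one. The bootstrap 95% interval of 0.644 to 1.09 resamples genes that move together and leaves out the spread between pairs, so it is too narrow. Macrophage medians by pair were 0.56, -0.26 and 0.23, against endothelial ones of -0.49, -0.85 and -0.86. The macrophage median was thus the higher one in each pair, but it lay below 0 in pair 2. Most other minor cell types had lower markers: median log2 fold changes were -0.79 for granulocytes and mast cells (5 genes), -0.52 for basal epithelium, -0.43 for pericytes, -0.39 for lymphocytes (2 genes), -0.33 for luminal epithelium, -0.27 for skeletal muscle and -0.17 for adipocytes, beside 0.22 for Schwann cells. The luminal list pointed upward without pair 3 (camera adjusted p 0.981), and the skeletal muscle list did so without pair 1 (0.219). A lower share of several minor cell types, macrophages and Schwann cells apart, therefore stays open. A lower share of endothelial cells in the Sharpin-cpdm cultures predicts 1 common fold, and 64.7% of 17 markers lay within 2 SE of their median, between the bounds set for and against it. Such a lower share, brought about by genotype or by the isolation, therefore stays open. It cannot be told apart from lower transcription in these cells, because RNA of whole cultures joins the share of a cell type and its level per cell. Markers closer to 1 common fold would not have settled this.

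The fall of Saa3, Serpina3n, Cfb, Hp and Ptx3 stayed at a median of -1.59 with the GC and length offsets, which argues against that bias. They were picked because they fell, and their median lay -0.832 from the endothelial one, with a bootstrap 95% interval over genes of -4.25 to 0.0463 that includes 0. A lower endothelial share alone can lower no gene by more than a gene made only by these cells. Markers that other cells also make fall by less, and Gpihbp1 and Cldn5 fell by more than the endothelial median. Saa3, Serpina3n, Cfb and Hp lay at -3.18 SDs from that median or further below it. The SDs join the gene SE and the SD over the markers. These genes were set apart from Ptx3, at 0.187 SDs, after their values were seen, so the distance is no independent test. Such a share as the whole cause therefore stays open for them and for Ptx3. A lower acute-phase programme as a whole is a hypothesis: of 17 further tested acute-phase genes, with a median of -0.39, 16 were lower, 6 fell (C4b, Cebpb, Steap4, Il1r1, Lbp and Serping1) and Serpina3g rose, by 1.13 ± 0.16. Of the 17, 6 (C3, C4b, Il6, Lcn2, Serping1 and Steap4) also belong to the fixed lists, and camera with an estimated correlation gave p = 0.188, so the programme as a whole stays open.

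The rise of Map3k14 could come from a chromosome segment carried along with the cpdm allele, but Map3k14 lies on chromosome 11 and Sharpin on chromosome 15. Within 10 Mb of Sharpin 7 of 217 tested genes were called, with 5.47 expected (one-sided Fisher's exact p = 0.307). Reads of an overlapping gene remain open, since 0 overlapping genes could be tested: 1700028N14Rik was not among the tested genes. Non-canonical NF-kappaB activity as the source or a consequence of the rise was tested on 6 further targets, 2 higher and 4 lower with 0 called, and camera with an estimated correlation gave p = 0.855. Their median of -0.18 met the bound set beforehand against it, but that bound was too loose, as so few members that go both ways decide nothing, and the question stays open.

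A further hypothesis concerns fibroblast subtypes. As Dpp4, Ly6a and Cd34 mark adventitial fibroblasts, fewer of these cells may lie behind the lower fibroblast markers. Of 14 other markers, of which Pi16, Wnt2 and Cd55 also belong to the fixed lists, 12 were lower with a median of -0.34. Ly6c1 alone fell, at -1.24 ± 0.20, and camera with an estimated correlation gave p = 0.184, which leaves the hypothesis open. Beside these, 14 of 19 endothelial markers fell, with a median log2 fold change of -0.78 over all 19. The test cannot show which cells the lower transcripts came from, so it does not tell these falls apart.

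The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. Without the block the real split called 0 genes and the highest of the others 0, so that all 10 gave as many. With the block, 4 splits part all 3 pairs, again too few; the real one called 337 genes and the highest of the others 0, and 1 of the 4 gave as many as the real one, itself.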
